A study of Homo sapiens with 3 samples.

How the data were processed

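Single-cell RNA sequencing libraries were made from neural organoids grown from H9, an established human embryonic stem cell line, per the labels. The 3 libraries were 1 of conventional midbrain organoids, 1 of midbrain organoids on an engineered perfusable scaffold, and 1 of such engineered organoids given 50 nM fentanyl, an opioid receptor agonist, for 2 days, with day 60 given in the series' design for the treatment. No day is given for the conventional and untreated engineered libraries, so a difference in age is not excluded. Organoids were dissociated with papain and loaded on the Chromium 3-prime chemistry, per the labels' protocols. Each group held 1 library, the labels gave no batch, and no sample was left out.

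The authors deposited, for each library, a matrix of UMI counts (1 value per gene and cell barcode), with 36601 genes. The matrices were written by Cell Ranger 7.1.0, per the file headers, and the values were whole numbers. The submitters' processing notes name the GRCh38 genome build, Seurat 4 and R 4.1.0. No header or label stated the annotation release, the cell calling or whether intronic reads were counted. Reads were not analysed here.

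Cells were kept with at least 500 genes, at least 1000 UMIs and at most 20% mitochondrial UMIs. Doublets were scored per library with the Scrublet method in scanpy 1.11.5. Its automatic threshold marked 3.98% of the engineered and 2.90% of the fentanyl library. It marked 1 cell (0.0127%) of the conventional library, under the 0.5% set as the sign of a failed call, and there the cells with the highest scores were left out at 0.8% per 1000 barcodes (6.69%). The limit on mitochondrial UMIs removed 9 conventional, 9 engineered and 3 fentanyl cells, and the doublet step removed 526, 378 and 251.

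The kept cells of all libraries were clustered together with no batch integration. Counts were scaled per cell and log-transformed, 3000 variable genes were chosen per library, and 30 principal components and 15 neighbours entered Leiden clustering at resolution 0.8 (igraph 0.11.9), which gave 23 clusters. Mitochondrial, ribosomal protein, X-inactivation and Y-linked genes and 8 response lists (hypoxia, glycolysis, stress responses, p53, heat shock, immediate early genes, respiratory chain and cholesterol synthesis) were kept out of the variable genes. Clusters were named from 21 marker sets. A marker passed at 1.5-fold over the other cells in at least 10% of the cluster's cells. A name needed at least 3 passing markers and 40% of its set, and either 1 marker among the 10 leading genes or 75% of the set. These naming thresholds were set after the data were seen, the marker sets before. Clusters that met no name, or whose leading genes held more markers of another class, stayed unnamed.

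UMIs were summed per library over all kept cells and over each class with at least 100 cells in both libraries, and were expressed as CPM, each gene's count scaled to the total of the cells summed. With 1 library per group no test across samples was possible, and neither p-values nor standard errors were computed. Each gene's ratio has an exact conditional binomial 95% interval, each level an exact Poisson interval and each share an exact Clopper-Pearson interval. Where a share was 0, the limit given is that of 3 cells of the total, which is lower than the Clopper-Pearson upper bound. UMIs of 1 cell and cells of 1 organoid are not independent, and all of these cover counting error only. A gene was counted as past the size rule at a 2-fold ratio, at least 50 CPM in the higher library and an interval that left out 1.

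Genes could be named from, per comparison in all cells, the 10 highest and 10 lowest ratios by that level and interval, and the 5 highest and 5 lowest in neuron-like and in progenitor-like cells. Mitochondrial, ribosomal protein, X-inactivation, Y-linked and clone-named genes were left out of these rankings. Of each gene list, up to 4 members with the largest ratio either way could be named, and any member of the opioid and dopaminergic lists. The comparisons, the alternatives planned, the 24 gene lists, the marker sets and the naming rule were fixed before the data were examined. The lists covered hypoxia-inducible factor targets, glycolysis, the unfolded protein and integrated stress response, p53 targets, heat shock chaperones, immediate early genes, nuclear and mitochondrial respiratory chain subunits, synapse, ion channels, dopaminergic, GABAergic and glutamatergic neurons, floor plate, opioid receptors and peptides, opioid signalling, cell division, astroglia, oligodendroglia, extracellular matrix, cholesterol synthesis, interferon and inflammation, Notch, WNT and hedgehog response, and axon growth. A list's value was the median log2 ratio of its members with at least 10 CPM in the higher library. Its percentile among 10000 random lists of the same size, matched on mean level, describes these libraries only. Members at least 1.5-fold higher or lower with an interval that left out 1 were counted.

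Shares of cells with a UMI of a gene were taken after thinning each cell to 2000 UMIs. Shallower cells were left out there, 847 conventional, 505 engineered and 397 fentanyl. Mesenchymal-like cells served as the class that should lack neuronal genes, and no class served so for CHAC1, a stress gene. Gene coordinates were matched by gene ID to GENCODE release 29 on GRCh38, which held all 261 named genes.

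The ratio step was tested on simulated counts for all 36601 genes. In each comparison 200 genes were changed, 50 in each direction at 2.5-fold and 50 at 3-fold. The changed genes were drawn from genes at 3 or more times the 50 CPM minimum. These were 1050 genes for engineered against conventional and 1036 for fentanyl against engineered. All 50 were recovered in each set, with 0 false calls, and the intervals held the true ratio for 95.4% and 95.6% of these 1050 and 1036 genes. At such levels and folds recovery had little room to fail, and changes near 50 CPM or near 2-fold were not tried. These simulations have counting error only.

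The same weight for each class was given to classes and unnamed clusters with at least 100 cells in both libraries. Alternatives fixed in advance were other cell filters, doublets kept, other scalings, the mean over cells, the same weight for each class, other level minimums, a 1.5-fold rule, other clustering resolutions, each library clustered alone and other thinning. Chosen after seeing the data were the alternatives without cluster 4, without clusters 2, 3 and 12, with the highest doublet scores left out in every library, and with cluster 12 counted as neuron-like. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.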

Results

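Gene expression in single cells was measured in neural organoids labelled midbrain, grown from the human embryonic stem cell line H9. The 3 groups, each with 1 library, were conventional organoids, engineered organoids on a perfusable scaffold, and engineered organoids treated with 50 nM fentanyl for 2 days. Day 60 is given for the fentanyl treatment only, so whether the other libraries are of the same age is not known. The conventional library held 62423652 UMIs in 8363 barcodes, the engineered library 84521257 in 9771, and the fentanyl library 85581659 in 8980. After filtering, 7331 conventional, 9111 engineered and 8394 fentanyl cells remained, with 54607706, 77704770 and 80585839 UMIs. Median UMIs per cell were 6389, 7266 and 8361.5, and median genes per cell 2919, 3121 and 3476. The median mitochondrial share was 2.70% in conventional, 3.83% in engineered and 3.06% in fentanyl cells, and the median ribosomal protein share 9.60%, 12.8% and 13.2%. No difference below has a replicate check, and all intervals are exact 95% intervals that cover counting error only. Levels are in CPM, UMI counts scaled to the total of the cells summed.

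Neuron-like cells, marked by genes such as STMN2 and DCX, were the largest named class of each library, at 37.0% (35.9 to 38.1) of conventional, 34.8% (33.9 to 35.8) of engineered and 36.9% (35.9 to 38.0) of fentanyl cells. Dividing cells, marked by MKI67 and TOP2A, were 4.92% (4.44 to 5.44) of conventional, 11.4% (10.8 to 12.1) of engineered and 16.6% (15.8 to 17.4) of fentanyl cells. Progenitor-like cells were 8.68%, 13.7% and 17.6%, and neuroblast-like cells 3.21%, 5.93% and 7.00%, in the same order. Floor plate-like cells, with SPON1 and SHH among their leading genes, were 0.491% of conventional, 3.97% of engineered and 3.81% of fentanyl cells. Mesenchymal-like cells, led by COL3A1 and COL1A1, were 0.941%, 1.46% and 2.80%. Leading genes of the floor plate-like, mesenchymal-like and progenitor-like clusters also differed between libraries, so their shares and those genes' levels are not separate observations. Different clusters held the progenitor-like class. Cluster 8, led by HOPX and PTN, held 7.34% of conventional cells and 0.209% of engineered cells, whereas cluster 7 held 1.08% and 9.49%. The differences in progenitor-like, neuroblast-like and neuron-like shares turned under other settings. When each library was clustered alone, the fentanyl minus engineered difference was −12.8 percentage points in progenitor-like and −3.84 in neuroblast-like cells. The engineered minus conventional difference was −5.97 in progenitor-like cells with stricter cell filters, and 1.85 in neuron-like cells after thinning to 2000 UMIs.

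Of the neuron-like cells, 27.4% of conventional, 23.5% of engineered and 25.5% of fentanyl cells lay in GABAergic-like clusters, and 31.3%, 34.8% and 27.7% in glutamatergic-like clusters. The other 41.3%, 41.7% and 46.8% lay in neuron clusters of unresolved transmitter type. No cluster met the marker rule for dopaminergic or serotonergic neurons. Unnamed clusters held 44.8% of conventional, 28.7% of engineered and 15.2% of fentanyl cells. The naming thresholds, set after the data were seen, kept cluster 5 out of every class with 7.98%, 9.75% and 4.77% of cells, cluster 6 with 7.11%, 8.09% and 2.41%, and cluster 12 with 4.77%, 2.46% and 2.32%. Cluster 5 had 6 passing progenitor and 4 passing ciliated markers, but no marker of either set among its leading genes. It held 888 engineered and 400 fentanyl cells, so the differences in progenitor-like shares depend on leaving it unnamed. Clusters 2 and 12 had median ribosomal protein shares of 1.60% and 1.17% and median depths of 2432 and 2725 UMIs. Cluster 4, here called the stress cluster, had CRYAB, GDF15, SLC2A1, P4HA1, NDRG1 and ADM among its leading genes and held 867 conventional, 368 engineered and 165 fentanyl cells. CRYAB took part in the clustering and differed between libraries, so these numbers are no measure of a cell type.

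**Figure D1:**
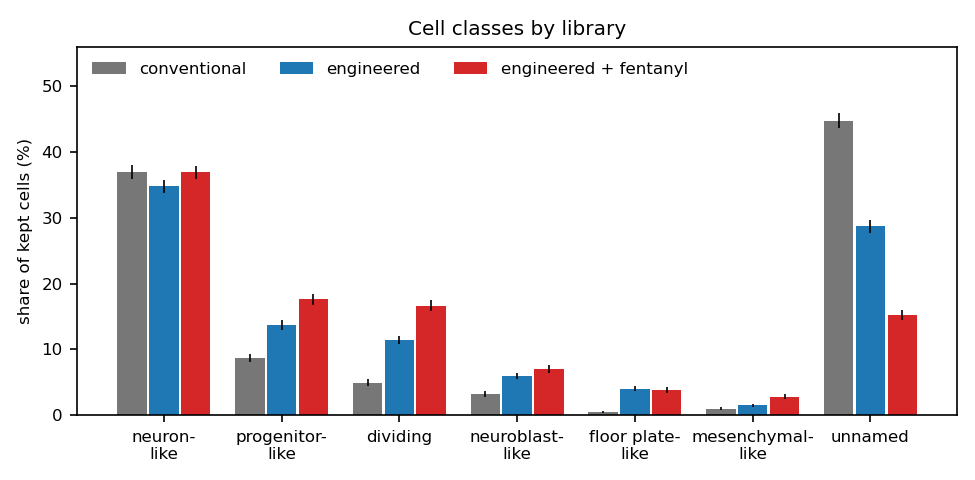
Share of kept cells (percent, vertical axis) in each cell class for the conventional, engineered and fentanyl libraries, as bars with exact 95% binomial intervals that cover counting error only. Neuron-like shares lie between 34.8% and 37.0%, and dividing cells are 4.92%, 11.4% and 16.6%.

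Engineered organoids were compared with conventional ones to ask how growth on a diffusible scaffold, the subject of the series' title, goes with the cells' expression. In the engineered library 11 of 14 cholesterol synthesis genes, 9 of 20 hypoxia-inducible factor targets and 7 of 14 unfolded protein and integrated stress response genes were lower past 1.5-fold, and 6 of 9 floor plate and 11 of 18 cell division genes were higher. The cell division median changed sign with the same weight for each class. CRYAB, a small heat shock protein, had 47.9 CPM in the engineered and 926 in the conventional library, 19.3-fold lower (18.7 to 19.99). TFPI2, a serine protease inhibitor, had 173 against 4.78, 36.2-fold higher (32.0 to 41.1). HMGCS1, an early enzyme of cholesterol synthesis, had 105 against 250, 2.37-fold lower (2.31 to 2.44). In all cells, 75 of 4316 genes at the level minimum (50 CPM in the higher library) were past the 2-fold rule, 44 higher and 31 lower. The split was 36 higher and 40 lower with the mean over cells, 27 and 29 with the same weight for each class, and 52 and 25 with median-of-ratios scaling.

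CRYAB (ENSG00000109846) lies on chromosome 11 of GRCh38, at 111908565 to 111923722 on the minus strand, TFPI2 (ENSG00000105825) on chromosome 7 at 93885396 to 93890991 on the minus strand, and HMGCS1 (ENSG00000112972) on chromosome 5 at 43289395 to 43313512 on the minus strand. Among genes at the level minimum, the highest ratios after TFPI2 were those of TTR, a thyroid hormone carrier (16.7-fold, 14.6 to 19.3), SLC5A7, the choline transporter of cholinergic neurons (13.1-fold, 11.6 to 14.9), and CMTM8 (10.0-fold, 8.89 to 11.4). SPON1, PDE10A, SKAP1, DLK1, PCSK1 and C5orf58 were 3.72-fold to 5.12-fold higher. Among genes at the level minimum, which GFAP and AGT (below) did not reach, the lowest ratios after CRYAB were those of HOPX, a radial glia gene (21.0 against 80.0 CPM, 3.80-fold lower, 3.59 to 4.03), and PTN, a secreted growth factor (3.26-fold lower, 3.22 to 3.29). ZNF385D, EPHA5, FABP7, CREB5, ERO1A, ELN and DDIT3 were 2.60-fold to 3.23-fold lower. Without the stress cluster, CRYAB had a log2 ratio of −2.67 in place of −4.27, and TTR 3.45 in place of 4.07. With the same weight for each class, which leaves out the floor plate-like and mesenchymal-like classes here because of few conventional cells, CMTM8 had 1.52 in place of 3.33, SPON1 1.24 in place of 2.36 and ZNF385D −1.05 in place of −1.69. With the mean over cells PDE10A had 1.47 in place of 2.07.

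All 14 measured cholesterol synthesis genes had a ratio below 1, 11 of them past 1.5-fold, with a median log2 ratio of −0.83 (percentile 0 among matched random lists). STARD4, a sterol carrier, was 2.53-fold lower (2.34 to 2.75), and MSMO1, a sterol oxidase, 2.52-fold lower (2.44 to 2.60). The median was −0.62 in neuron-like, −1.53 in progenitor-like and −1.08 in dividing cells. The progenitor-like medians of this list and of the hypoxia and glycolysis lists below compare largely different clusters. Cluster 8 held 538 conventional and 19 engineered cells, and cluster 7 held 79 and 865. Of 20 hypoxia-inducible factor targets, 9 were lower and 0 higher (median −0.45, percentile 0). ADM, a vasodilator peptide, was 3.61-fold lower (3.28 to 3.97), the oxidase ERO1A 2.68-fold lower (2.56 to 2.79), and NDRG1 2.62-fold lower (2.40 to 2.86). Without the stress cluster the hypoxia median was −0.11, ADM had a log2 ratio of −0.08, ERO1A one of −0.28 and NDRG1 one of 0.14. The hypoxia median was −0.20 in neuron-like cells (percentile 2.06, 0 of 16 genes past 1.5-fold), −0.09 in progenitor-like cells (percentile 43.4, 2 higher, 3 lower) and 0.19 in dividing cells (percentile 99.5, 4 higher, 0 lower). Of 17 glycolysis genes 2 were lower, HK2 (1.76-fold, 1.64 to 1.90) and LDHA (1.69-fold, 1.64 to 1.75), with a median of −0.11 (percentile 14.8) that was 0.23 without the stress cluster and 0.03 with the same weight for each class. Without the stress cluster the log2 ratios of HK2 (0.40) and LDHA (0.05) were above 0. Within classes the glycolysis median was 0.19 in neuron-like cells (percentile 99.7, 0 past 1.5-fold), 0.27 in progenitor-like cells (percentile 99.8, 5 higher, 1 lower), 0.39 in dividing cells (percentile 100, 6 higher, 0 lower) and 0.06 in neuroblast-like cells (percentile 87.9).

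Of 14 unfolded protein and integrated stress response genes, 7 were lower and 0 higher (median −0.48, percentile 0). DDIT3, a stress-induced transcription factor, was 2.60-fold lower (2.502 to 2.69), and HSPA5, the main chaperone of the endoplasmic reticulum, 2.16-fold lower (2.12 to 2.20). Without the stress cluster their log2 ratios were −0.82 in place of −1.38 and −0.46 in place of −1.11, and with the same weight for each class that of DDIT3 was −0.75. The list median was −0.15 without the stress cluster, −0.28 with the mean over cells and −0.29 with the same weight for each class. Of 15 p53 targets and apoptosis genes 4 were lower (median −0.41, percentile 0), among them GDF15 (2.52-fold, 2.42 to 2.62) and CDKN1A, a cell cycle inhibitor (2.05-fold, 1.96 to 2.15). The median was −0.25 with the same weight for each class, and without the stress cluster the log2 ratio of GDF15 turned from −1.33 to 0.19. Of 12 heat shock chaperones 4 were lower (median −0.32, percentile 0.05), with HSPB1 1.87-fold lower (1.81 to 1.92), and the median was −0.14 with the mean over cells. The 8 measured immediate early genes had a median of 0.01 in all cells (percentile 80.2) and 0.34 in neuron-like cells (percentile 99.9, 2 higher, 0 lower). Nuclear respiratory chain genes had a median of 0.07 (16 genes, percentile 61.4) and mitochondrially encoded ones 0.37 (13 genes, 2 higher, percentile 100). Beside these values stand the higher mitochondrial and ribosomal protein shares and the greater depth of the engineered library.

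Of 9 floor plate genes, 6 were higher and 0 lower (median 1.35, percentile 100). SHH, the ventral midline signal, was 10.8-fold higher (8.80 to 13.4), and the transcription factor FOXA1 6.74-fold higher (5.44 to 8.44), or a log2 ratio of 1.04 in place of 2.75 with the same weight for each class. The median was 0.79 with the mean over cells and 0.32 with the same weight for each class, which leaves out the floor plate-like class because the conventional library held 36 such cells. Of 18 cell division genes 11 were higher (median 0.66, percentile 100), among them AURKB (1.85-fold, 1.72 to 1.99) and UBE2C (1.77-fold, 1.72 to 1.82). These go with the share of dividing cells, 11.4% against 4.92%. The median was −0.06 with the same weight for each class, and the log2 ratios of AURKB and UBE2C were 0.07 and −0.20. The list median was 0.91 within progenitor-like cells, −0.28 within dividing cells (0 higher, 4 lower) and −0.63 within neuroblast-like cells (6 of 12 lower). The progenitor-like value again compares largely different clusters. Of 12 astroglial genes 3 were lower and 1 higher (median −0.42, percentile 0). GFAP, an intermediate filament of astrocytes, had 0.901 against 20.03 CPM, 22.2-fold lower (17.5 to 28.7), AGT was 4.63-fold lower (4.03 to 5.33), and ID3 was 1.81-fold higher (1.78 to 1.83). The 2 measured oligodendroglial genes had a median of −0.81 (percentile 0.52) that was above 0 under 5 alternatives.

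Synaptic genes had a median of −0.31 in all cells (25 genes, 1 higher, 3 lower, percentile 0) and −0.04 in neuron-like cells (30 genes, percentile 24.3). The glutamate receptor subunit GRIN2B was 2.01-fold lower (1.90 to 2.13) and the GABA receptor subunit GABRA2 1.87-fold higher (1.75 to 2.00). The synapse median was −0.14 with the same weight for each class. Ion channel genes had a median of −0.23 (18 genes, 2 higher, 5 lower, percentile 3.19), with the calcium channel CACNA1E 2.30-fold lower (2.15 to 2.45). This median was −0.41 with the mean over cells and −0.03 with the same weight for each class. GABAergic genes had a median of −0.05 (4 genes, percentile 59.4) and glutamatergic genes 0.02 (6 genes, percentile 70.7). Extracellular matrix genes had a median of 0.14 (18 genes, 1 higher, percentile 99.7), interferon and inflammation genes 0.22 (7 genes, 2 higher, percentile 98.2), and Notch, WNT and hedgehog genes 0.13 (11 genes, 1 higher, percentile 97.3). With the same weight for each class these were −0.09, −0.07 and −0.17, but that setting leaves out the mesenchymal-like class, led by collagen genes, because the conventional library held 69 such cells. The interferon-induced genes IFI6 and ISG15 were 3.41-fold (3.22 to 3.61) and 2.76-fold higher (2.55 to 2.99). Axon growth genes had a median of 0.09 (18 genes, 2 higher, 1 lower, percentile 90.3), and opioid signalling genes 0.04 (29 genes, 2 higher, 2 lower, percentile 91.4).

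Within neuron-like cells, 38 genes were higher and 34 lower past the 2-fold rule, of 4342. PCP4, a calmodulin-binding protein, was 6.45-fold higher (5.58 to 7.49), VGF, a secreted neuropeptide precursor, 4.24-fold (3.81 to 4.73), and HOXC4, a homeobox gene of posterior identity, 3.37-fold (3.09 to 3.67). ZFHX4-AS1 and ZNF503 were 3.16-fold and 3.15-fold higher. CRYAB was 14.1-fold lower (11.1 to 18.2), the transcription factor NFIB 6.28-fold (5.95 to 6.64), ZNF385D 5.49-fold (5.14 to 5.87), the netrin receptor UNC5C 3.77-fold (3.51 to 4.05) and FABP7 3.32-fold (3.07 to 3.60). ZNF385D leads neuron cluster 0, which held 7.76% of conventional and 0.823% of engineered cells, and PCP4 leads neuron cluster 11, which held 7.52% and 13.7%, so their ratios go with the mix of neuron clusters. Within progenitor-like cells, where clusters 8 and 7 hold most conventional and engineered cells respectively, 67 genes were higher and 193 lower of 4211. TFPI2, CPNE4, SST, ADAMTS17 and DLK1 were 12.6-fold to 124-fold higher, and GABBR2, PI15, BCAN and FABP7, the last a radial glia gene, were 9.02-fold to 15.1-fold lower. In dividing cells 69 genes were higher and 65 lower, and in neuroblast-like cells 78 and 69.

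**Figure D2:**
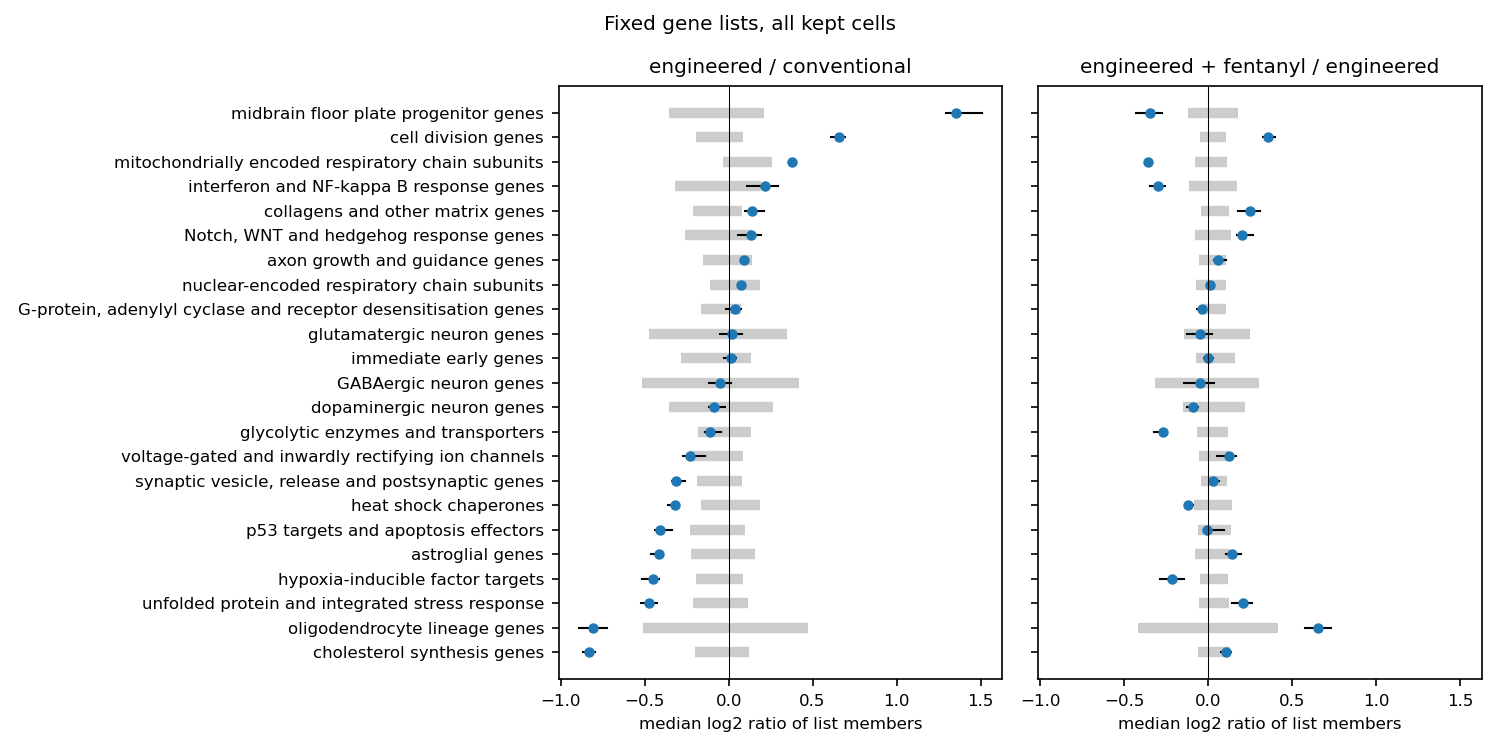
Median log2 ratio of each gene list (horizontal axis) in all cells for engineered against conventional and for fentanyl against engineered, as points, with the middle 95% of 10000 matched random lists as bars. In the engineered library the cholesterol list (−0.83) and the hypoxia list (−0.45) lie below their bars, and in the fentanyl library the stress response list (0.20) lies above its bar.

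Fentanyl-treated engineered organoids were compared with untreated engineered ones to ask how exposure to an opioid goes with expression. In the fentanyl library 5 of 15 unfolded protein and integrated stress response genes and 3 of 11 Notch, WNT and hedgehog response genes were higher, and TFPI2 had the lowest ratio of the genes at the level minimum. HHIP, a hedgehog-binding protein and itself a hedgehog target, had 207 CPM in the fentanyl and 48.8 in the engineered library, 4.24-fold higher (4.09 to 4.39). CHAC1, a glutathione-degrading enzyme induced by the integrated stress response, had 23.2 against 6.14, 3.78-fold higher (3.41 to 4.18). TFPI2 had 4.52 against 173, 38.3-fold lower (34.5 to 42.6). Its level in the conventional library (above) was also far below that of the engineered library, so the engineered library stands apart from both others. In all cells, 37 of 4091 genes were past the 2-fold rule, 12 higher and 25 lower, and 15 genes with the same weight for each class.

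HHIP (ENSG00000164161) lies on chromosome 4 of GRCh38 at 144646021 to 144745271 on the plus strand, where its antisense gene HHIP-AS1 is also annotated, and CHAC1 (ENSG00000128965) on chromosome 15 at 40952962 to 40956519 on the plus strand. Among genes at the level minimum of 50 CPM, which CHAC1 did not reach, and with clone-named genes left out, the highest ratios after HHIP were those of the cystine transporter SLC7A11 (108 against 39.0 CPM, 2.76-fold, 2.65 to 2.88), HHIP-AS1 (2.48-fold, 2.35 to 2.63), FGFBP3 (2.26-fold, 2.15 to 2.38) and the serine synthesis enzyme PSAT1 (2.15-fold, 2.09 to 2.21). EIF4EBP1, CEBPB, TTR, PMAIP1 and APOE were 2.00-fold to 2.07-fold higher. The lowest ratios after TFPI2 were those of SLC5A7 (12.9-fold lower, 11.6 to 14.2), DLK1 (6.71-fold, 6.47 to 6.96), C5orf58 (4.99-fold, 4.78 to 5.21), GNG11 (4.66-fold, 4.50 to 4.83) and PDE10A (3.89-fold, 3.79 to 3.98). SKAP1, the WNT inhibitor DKK1, PCSK1 and LY6H were 2.90-fold to 3.46-fold lower. TFPI2, SLC5A7, DLK1, C5orf58, GNG11, PDE10A, SKAP1 and PCSK1 were also past the 2-fold rule higher in the engineered than in the conventional library. C5orf58, DKK1 and PCSK1 are leading genes of cluster 6. With the same weight for each class, log2 ratios nearer 0 were those of DKK1 (−0.44 in place of −1.72), PCSK1 (−0.59 in place of −1.65), C5orf58 (−1.18 in place of −2.32), LY6H (−0.74 in place of −1.54), SLC7A11 (0.69 in place of 1.46) and APOE (0.30 in place of 1.00). Of these only C5orf58 stayed past 2-fold.

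Of 15 unfolded protein and integrated stress response genes, 5 were higher and 0 lower (median 0.20, percentile 99.99). TRIB3 was 2.20-fold higher (2.08 to 2.34), SESN2 1.93-fold (1.83 to 2.03) and HERPUD1 1.66-fold (1.61 to 1.70). The median was 0.10 with the mean over cells, 0.13 with the same weight for each class and 0.31 without the stress cluster. Within classes it was 0.34 in neuron-like cells (7 of 16 higher), 0.35 in progenitor-like cells (5 of 15 higher), 0.93 in dividing cells (8 of 15 higher) and 0.39 in mesenchymal-like cells (6 of 14 higher). It was 0.08 in neuroblast-like cells and −0.29 in floor plate-like cells, where 5 of 14 genes were lower. In engineered against conventional cells this list had a median of −0.48, and it was not compared between fentanyl and conventional. Whether the fentanyl library is above the conventional one for this list is therefore not known. Of 11 Notch, WNT and hedgehog response genes 3 were higher (median 0.20, percentile 99.9), HHIP, the hedgehog receptor PTCH1 (1.90-fold, 1.84 to 1.97) and the Notch target HES5 (1.72-fold, 1.68 to 1.76).

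Of 19 hypoxia-inducible factor targets 5 were lower and 1 higher (median −0.22, percentile 0). NDRG1 was 1.88-fold lower (1.67 to 2.12) and DDIT4, which stress responses also induce, 1.74-fold higher (1.71 to 1.78). The hypoxia median was −0.09 without the stress cluster and −0.07 with the mean over cells. Of 17 glycolysis genes 2 were lower (median −0.27, percentile 0), HK2 (1.64-fold, 1.504 to 1.79) and the lactate transporter SLC16A3 (1.60-fold, 1.47 to 1.74), and the median was −0.47 with the same weight for each class. The 13 mitochondrially encoded respiratory chain genes had a median of −0.36 (percentile 0), or −0.17 with the same weight for each class, and the 16 nuclear ones 0.01 (percentile 39.8). The median mitochondrial share was 3.06% in fentanyl and 3.83% in engineered cells, so the mitochondrially encoded median is not a separate observation. Of 11 heat shock chaperones 1 was lower, HSPA1A (1.70-fold, 1.59 to 1.81), with a median of −0.12 (percentile 0.88). The p53 list had a median of −0.01 (15 genes, 1 higher, 1 lower, percentile 18.5), with PMAIP1 2.03-fold higher (1.93 to 2.14) and GDF15 1.82-fold lower (1.73 to 1.92). The 8 immediate early genes had a median of −0.00034 (percentile 23.9).

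Cell division genes had a median of 0.36 (18 genes, 0 past 1.5-fold, percentile 100), or 0.12 with the same weight for each class and −0.02 within dividing cells, with MKI67 1.48-fold higher (1.43 to 1.54). Of 18 extracellular matrix genes 4 were higher (median 0.25, percentile 100), with COL3A1 1.97-fold (1.93 to 2.00) and COL1A1 1.96-fold higher (1.91 to 2.01). These go with the share of mesenchymal-like cells, 2.80% against 1.46%, and with the same weight for each class the median was −0.16. Of 7 interferon and inflammation genes 3 were lower (median −0.30, percentile 0.06), with IFI6 2.22-fold (2.13 to 2.32) and ISG15 1.70-fold lower (1.61 to 1.81). Floor plate genes had a median of −0.35 (9 genes, 1 lower, percentile 0.01), or −0.06 with the same weight for each class, with LMX1A 1.97-fold lower (1.85 to 2.10), or a log2 ratio of −0.12 with the same weight. The floor plate-like share was 3.81% in fentanyl and 3.97% in engineered cells, and FOXA2 had 2.35 and 2.24 CPM. LMX1A had 29.4 CPM in the conventional library, where 0.491% of cells were floor plate-like, so its level is no measure of that class. Astroglial genes had a median of 0.14 (10 genes, 1 higher, 1 lower, percentile 98.5) and the 2 oligodendroglial genes 0.66 (percentile 99.6). Synaptic genes had a median of 0.03 (25 genes, 1 lower, percentile 40.5), ion channel genes 0.13 (18 genes, 1 higher, 2 lower, percentile 97.7) and axon growth genes 0.06 (18 genes, 1 lower, percentile 75.9). GABAergic genes had a median of −0.05 (3 genes, percentile 29.4), glutamatergic genes −0.05 (4 genes, percentile 11.8), and cholesterol synthesis genes 0.11 (14 genes, percentile 92.5).

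Within neuron-like cells, 3 genes were higher and 6 lower past the 2-fold rule, of 4161. The serine synthesis enzymes PHGDH and PSAT1 were 2.26-fold (2.06 to 2.48) and 2.08-fold higher (1.90 to 2.28), and the stress-induced transcription factor ATF5 2.02-fold (1.91 to 2.14). The tyrosyl-tRNA synthetase YARS and the mitochondrial folate enzyme MTHFD2 were 1.82-fold and 1.81-fold higher. ANXA2, S100A10, ID1, PRPH and DLK1 were 2.29-fold to 2.79-fold lower. PRPH is a leading gene of neuron cluster 22, which held 18 engineered and 2 fentanyl cells at a median depth of 40797 UMIs. Whether any of these ratios rests on such few deep cells was not tested. CHAC1 had 40.05 against 9.95 CPM in these cells, 4.03-fold higher (3.43 to 4.75). At 2000 UMIs per cell, a CHAC1 UMI was found in 2.42% (1.83 to 3.15) of conventional, 1.75% (1.30 to 2.29) of engineered and 7.25% (6.34 to 8.25) of fentanyl neuron-like cells. In mesenchymal-like cells it was found in 0 of 65 conventional cells, which allows up to 4.62%, 0 of 129 engineered cells, which allows up to 2.33%, and 0.905% of fentanyl cells. Unthinned, the neuron-like shares were 5.97%, 5.20% and 19.0%, at median depths of 4631, 5417 and 6501.5 UMIs, and the mesenchymal-like shares 11.6%, 0 of 133 cells (up to 2.26%) and 5.11%, at 19188, 12604 and 15300. Mesenchymal-like cells can express this stress gene too, so their shares set no background for it. Within progenitor-like cells 26 genes were higher and 28 lower of 3886. HHIP was 5.32-fold (4.93 to 5.76) and SLC7A11 4.24-fold higher (3.76 to 4.80), DGKB, CNTNAP5 and FGFBP3 were 2.75-fold to 2.90-fold higher, and TFPI2, ADAMTS17, SST, CPNE4 and KIRREL3 were 8.03-fold to 66.3-fold lower. Past the 2-fold rule were 59 genes in dividing, 67 in floor plate-like, 29 in neuroblast-like and 23 in mesenchymal-like cells.

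No opioid receptor or peptide gene reached 10 CPM in all cells of any library. OPRM1, the mu receptor on which fentanyl acts, had 2.69 CPM in conventional, 3.58 in engineered and 3.18 in fentanyl cells. OPRM1 was 1.13-fold lower (0.947 to 1.34) in fentanyl than in engineered cells, a difference not detectable at this depth. In neuron-like cells OPRM1 had 6.55, 10.4 and 9.26 CPM, and a UMI was found in 1.30%, 1.88% and 1.93% of them at 2000 UMIs (2.65%, 4.06% and 4.33% unthinned, at the median depths above). Mesenchymal-like cells had 0 of 65, 0 of 129 and 0 of 221 cells with an OPRM1 UMI, which allows up to 4.62%, 2.33% and 1.36%. Unthinned, they had 0 of 69 (up to 4.35%), 1 of 133 (0.752%) and 4 of 235 (1.70%). OPRK1 had 2.64, 2.73 and 3.50 CPM, OPRD1 0.586, 0.515 and 0.397, and OPRL1 1.54, 1.09 and 0.968. Of the peptide precursors, POMC had 1.12, 3.69 and 7.42 CPM, PENK 1.85, 4.86 and 6.86, and PNOC 2.88, 5.46 and 6.69. With the same weight for each class, the log2 ratio of POMC was 0.35 in place of 1.73 for engineered against conventional. For fentanyl against engineered, that of POMC was 0.20 in place of 1.01 and that of PENK 1.10 in place of 0.50. At 2000 UMIs a PENK UMI was found in 0.449%, 0.274% and 0.102% of neuron-like cells, and a PNOC UMI in 1.26%, 2.67% and 3.32%. PDYN had no UMI in the conventional library, 0.116 in engineered and 0.0993 in fentanyl cells. The opioid signalling list had a median of −0.04 in fentanyl against engineered cells (28 genes, 2 lower, percentile 2.00), the lower genes being the phosphodiesterases PDE10A (3.89-fold) and PDE4B (1.87-fold, 1.83 to 1.91).

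Of 18 dopaminergic genes, 4 reached 10 CPM in all cells. TH, the rate-limiting enzyme of dopamine synthesis, had 0.458 CPM in conventional, 1.74 in engineered and 1.08 in fentanyl cells. At 2000 UMIs a TH UMI was found in 0.269% (0.0989 to 0.585), 0.959% (0.638 to 1.38) and 0.373% (0.186 to 0.666) of neuron-like cells, or 0.516%, 2.17% and 1.74% unthinned, and in 0 of 65, 0 of 129 and 0 of 221 mesenchymal-like cells at 2000 UMIs and 0 of 69, 0 of 133 and 0 of 235 unthinned. The transcription factor NR4A2 had 7.09, 8.43 and 8.35 CPM, EN1 0.128, 1.70 and 4.63, LMX1B 5.04, 2.68 and 4.03, and PITX3 0.0732, 0.0257 and 0.0372. The transporters SLC6A3 and SLC18A2 had 0.128, 0.103 and 0.137, and 4.30, 4.53 and 3.56. DDC had 0.128, 0.669 and 1.19 CPM, ALDH1A1 1.12, 0.656 and 0.608, EN2 7.36, 6.01 and 3.82, RET 3.48, 3.00 and 1.43, DRD2 1.06, 1.31 and 1.04, GCH1 2.34, 2.56 and 2.28, and CALB1 2.55, 4.98 and 3.52. SNCG had 47.5, 94.5 and 79.95 CPM, SOX6 145, 99.5 and 103, and KCNJ6 19.5, 13.6 and 14.8. The 4 members at the level minimum, these 3 among them, gave list medians of −0.08 in engineered against conventional cells (1 higher, percentile 37.9) and −0.09 in fentanyl against engineered cells (0 past 1.5-fold, percentile 7.63). SNCG is a leading gene of progenitor-like cluster 14, which held 0.259% of conventional, 4.00% of engineered and 5.66% of fentanyl cells. SOX6 is one of unnamed cluster 2, which held 4.83%, 1.09% and 1.52%, and LMX1B one of glutamatergic-like cluster 9. These levels and medians are therefore no measure of dopaminergic neurons.

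The engineered library is in both comparisons. Of 3952 genes at the level minimum in both, 10 were past the 2-fold rule higher in the engineered than in the conventional library and lower with fentanyl, C5orf58, DLK1, GNG11, IFI6, PCSK1, PDE10A, PDE3A, SKAP1, SLC5A7 and TFPI2. Independent lists of these sizes would share 0.278 genes, and 100 simulations of unchanged libraries shared 0. The simulations have counting error only, under which the ratio step gave 0 false calls, so their 0 was fixed beforehand, and the independent value leaves out the shared library. Neither is the overlap expected with no effect. The level minimum in both comparisons kept all 44 genes higher in the engineered library and all 25 lower with fentanyl, but 15 of the 31 lower in the engineered library and 4 of the 12 higher with fentanyl, so overlaps in the other directions are not compared. Part or all of the overlap may come from the shared engineered library, which cannot be split.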

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

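The alternatives without the stress cluster (cluster 4), without clusters 2, 3 and 12, with the highest doublet scores left out in every library and with cluster 12 counted as neuron-like were chosen after seeing the data, and the others were planned. Of 38 gene counts 31 stayed within 1.5 times, of 786 list medians 582 stayed within their counting interval, and of 2530 ratios of named genes 1983 stayed. Of the list medians 64 changed sign, 9 of them for lists outside the middle 95% of random lists, and of the ratios 41 changed sign, 16 of them for genes whose interval left out 1. The values of these 9 and 16 are given below. Of 69 differences in shares of other classes 51 stayed, of 16 in the neuron-like share 11 stayed, and of 60 shares of cells with a UMI 18 stayed. No paired analysis was possible because each group had 1 library and no result comes from a test. For the same reason no replicate could be left out. Depth limits the opioid genes, none of which reached the level minimum in all cells.

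Counts past the size rule, with 75 for engineered against conventional and 37 for fentanyl against engineered, were 174 and 75 with a minimum of 20 CPM, 2267 and 1062 with no minimum, and 300 and 150 at 1.5-fold, since more genes can pass by construction. With the same weight for each class the count for fentanyl against engineered was 15.

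The hypoxia median for engineered against conventional (−0.45) was −0.11 without the stress cluster, −0.37 with median-of-ratios scaling, −0.41 with totals without mitochondrial and ribosomal protein genes and −0.42 with the same weight for each class. For fentanyl against engineered (−0.22) it was −0.091 without the stress cluster, −0.074 with the mean over cells and −0.33 with the same weight. The synapse median for engineered against conventional (−0.31) was −0.37 without the stress cluster, −0.21 without clusters 2, 3 and 12, −0.22 with median-of-ratios scaling, −0.25 with totals without mitochondrial and ribosomal protein genes, −0.14 with the same weight and −0.24 with no level minimum. For fentanyl against engineered (0.03) it was 0.0094 with median-of-ratios scaling, 0.071 with the mean over cells and 0.14 with the same weight. The cause was not tested. The same weight for each class changes the mix of classes and also leaves out those with under 100 cells in either library, which were cluster 2 and the floor plate-like and mesenchymal-like classes for engineered against conventional and clusters 1 and 2 for fentanyl against engineered, so what it moved cannot be put down to the mix alone.

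In engineered against conventional cells the oligodendroglial median turned to 0.21 with doublets kept, 0.13 without the stress cluster, 0.29 with median-of-ratios scaling, 0.26 with totals without mitochondrial and ribosomal protein genes and 0.19 with no level minimum. With the same weight for each class the cell division median turned to −0.064, extracellular matrix to −0.088, interferon to −0.073, and the log2 ratios of IFI27 to −0.073 and UBE2C to −0.20. Without the stress cluster the log2 ratios of ALDOA (0.059), CYCS (0.035), GDF15 (0.19), HK2 (0.40), LDHA (0.054), NDRG1 (0.14) and SLC2A3 (0.34) turned, and with the mean over cells that of OPRM1 (−0.030). In fentanyl against engineered cells the same weight turned extracellular matrix (−0.16), COL1A1 (−0.10), COL3A1 (−0.10), COL6A3 (−0.39), FN1 (−0.24), ROBO1 (0.0089) and SOX6 (−0.047). The cause was not tested.

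The neuron-like difference between engineered and conventional (−2.16 percentage points) was −0.484 with stricter filters, −5.79 with doublets kept, −4.47 with cluster 12 counted and 1.85, of opposite sign, after thinning to 2000 UMIs. Between fentanyl and engineered (2.07) it was 4.72 after thinning. The progenitor-like difference turned to −5.97 for engineered against conventional with stricter filters, and to −12.8 for fentanyl against engineered with each library clustered alone, where the neuroblast-like difference turned to −3.84. The cause was not tested.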

Other observations

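The tests without the stress cluster, without clusters 2, 3 and 12, of the mix of classes, of dissociation and of free RNA were chosen after the result was seen, and the gene lists used below were chosen after other results were seen.

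HOX genes, which pattern the hindbrain and spinal cord and are silent in the midbrain, were detected in all 3 libraries. Of 39 HOX genes, 24 had at least 10 CPM in every library. HOXB9 had 203 CPM in conventional, 400 in engineered and 424 in fentanyl cells, HOXB8 130, 156 and 153, HOXA5 69.4, 132 and 124, and HOXC10 24.9, 55.4 and 49.5. The forebrain and midbrain gene OTX2 had 0.110, 0.167 and 0.347, and the floor plate gene FOXA2 0.0366, 2.24 and 2.35. At 2000 UMIs per cell, any HOX UMI was found in 73.8% of conventional, 95.9% of engineered and 97.4% of fentanyl neuron-like cells, in 11.8%, 26.5% and 23.4% of floor plate-like cells, and in 15.4%, 14.0% and 10.4% of mesenchymal-like cells. The mix of neuron clusters differed, with 569 conventional, 75 engineered and 31 fentanyl cells in neuron cluster 0. HOX shares per cluster were not taken, so whether the lower conventional share goes with that mix was not tested. Unthinned, a HOXB9 UMI was found in 48.6%, 81.6% and 85.5% of neuron-like cells, at median depths of 4631, 5417 and 6501.5 UMIs, and in 7.25%, 9.77% and 11.5% of mesenchymal-like cells, at 19188, 12604 and 15300.

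HOX genes were thus detected in libraries labelled midbrain. Free RNA from a few HOX-positive cells, if of like amount per droplet, gives every class a like share before thinning. The unthinned HOXB9 shares argue against it as the source. They were 7.25% of conventional, 9.77% of engineered and 11.5% of fentanyl mesenchymal-like cells, against 48.6%, 81.6% and 85.5% of neuron-like cells. At 2000 UMIs a HOXB9 UMI was found in at most 3.17% of mesenchymal-like cells of any library, against 42.2%, 69.3% and 70.9% of neuron-like cells. Thinning lowers free RNA more in the deeper mesenchymal-like cells, so the thinned contrast alone cannot decide this. A midbrain neuron population among the neuron-like cells without a HOX UMI stays open: at most 2.56% of them in any library had a TH, EN1, OTX2 or PITX3 UMI (2 of 584, 0 of 120 and 2 of 78 cells), but cells with a HOX UMI had like shares (0.365%, 1.75% and 2.23%), and the bound of 10% set for the test had no midbrain population to rest on. At 2000 UMIs a HOX UMI was found in 73.8% of conventional, 95.9% of engineered and 97.4% of fentanyl neuron-like cells. HOX genes are silent in the midbrain, so these shares argue against a midbrain identity for most neuron-like cells of each library. An OTX2 UMI was found in 0 of 2227, 0 of 2919 and 0 of 2951 neuron-like cells. That most neuron-like cells of these libraries may have a hindbrain or spinal identity remains a hypothesis. Whether the labels name the intended region or a measured one cannot be read from these data, and no biological explanation was tested.

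Of 20 hypoxia-inducible factor targets 9 were lower in the engineered than in the conventional library (median log2 ratio −0.45), although the median within dividing cells was 0.19. Barcodes of low depth (clusters 2 and 12) or high ribosomal share (cluster 3) are argued against, since the median was −0.459 without clusters 2, 3 and 12. Without the stress cluster it was −0.113, inside the range of random lists (−0.21 to 0.08), and within the stress cluster it was −0.618, below that range (from −0.25), with 12 of 22 genes lower. Fewer cells in that cluster and a lower level within it are therefore both candidate explanations. Hypoxia genes are among the cluster's leading genes, however, so removing it takes out cells in which they are high. Better supply through the scaffold stays open and untested, as does any difference between single libraries in dissociation or cell selection.

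In the fentanyl library 5 of 15 stress response genes were higher (median 0.20). A change in the mix of classes as the whole of it is argued against by medians of at least 0.335 within neuron-like, progenitor-like and dividing cells, although the median was 0.08 in neuroblast-like and −0.29 in floor plate-like cells and 0.13 with the same weight for each class. A response to dissociation that raises heat shock chaperones is also argued against, by a heat shock median of −0.119. The immediate early median (above) was not higher than random lists either, but a handling difference that raises other genes was not tested. A low engineered library is argued against only for ATF4 targets in neuron-like cells, by their median of 0.408 in fentanyl against conventional. For the stress response list it stays open, since that median was −0.475 in engineered against conventional (7 of 14 lower). The list was not compared between fentanyl and conventional. The hypothesis of ATF4, the transcription factor that amino acid shortage and other stresses induce, was tested on 25 other ATF4 targets, and their median in neuron-like cells was 0.558 (random lists up to 0.09, 9 of 24 higher), whereas 14 endoplasmic reticulum chaperones, 6 of them also in the stress response list, had a median of −0.189, which argues against a response of these chaperones. An ATF4 response may therefore describe this library, and whether fentanyl, the medium on that day or another difference between 2 single libraries underlies it was not tested, since each group held 1 library.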
